A study of Mus musculus with 16 samples.

How the data were processed

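RNA-seq was measured in 8 libraries of J1 mouse embryonic stem (ES) cells in 4 groups of 2, and chromatin immunoprecipitation with sequencing (ChIP-seq) for histone H3 acetylated at lysine 27 (H3K27ac) in 4 libraries of pachytene spermatocytes, 2 from wild-type mice and 2 from A-myb mutant mice. The 4 input libraries of the spermatocytes were not analysed here. Which library served as treatment and which as control in each peak call is not given in the sources used here, nor is the role or setting of each tool.

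The deposited ES cell files hold raw counts, whole numbers of reads per gene symbol, with no normalization; they end in 5 special lines for reads assigned to no gene, which were kept out of the gene table. Per the labels, the submitters' processing notes name bcl2fastq 2.20.0, HISAT2 2.1.0, HTSeq without a version, Bowtie2 2.3.3.1, MACS 1.4.2 and the genome build mm10. The deposited peak lists give, for every peak, the number of tags as counts, a score, and the enrichment as a ratio (fold over background). The heading of the score column calls it a negative log10 p, but its values start at 50, the scale that MACS 1.4 writes as -10 times log10 p; it is called the score here and was used only to rank peaks. The other values in the authors' peak lists are positions in mm10.

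The ES tables hold 23420 genes, of which 18917 had at least 1 count and 14664 passed edgeR's filterByExpr on the 4 groups and were tested. Counts were scaled by TMM (trimmed mean of M values) and fitted with edgeR 4.0.16 (glmQLFit, robust, in 1 model with a coefficient per group and 4 residual degrees of freedom; limma 3.58.1, R 4.3.3). Contrasts were tested two-sided with glmQLFTest and Benjamini-Hochberg adjusted over the 14664 genes, and an adjusted p under 0.05 passed. The contrasts were the Dox effect without and with A-MYB, the A-MYB effect without and with Dox, and their interaction, the Dox effect with A-MYB minus that without. The Dox effects with and without A-MYB share no library, and neither do both A-MYB effects. A Dox effect and an A-MYB effect do share libraries. Dox without A-MYB and A-MYB without Dox share the libraries with neither treatment. Dox with A-MYB and A-MYB with Dox share the libraries with both. Changes that such a pair has in common are thus not independent findings. Levels are edgeR's CPM, the counts of a gene scaled to the TMM-adjusted library size, as mean ± SD of n = 2. Log2 fold changes are edgeR's. For the genes treated in full they are given with a standard error (SE), which edgeR does not report. It was derived as the absolute log2 fold change divided by the square root of the F statistic of glmQLFTest.

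The groups, contrasts, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined. The rule takes Mybl1, and per contrast the 10 genes with the largest increase and the 10 with the largest decrease among those that passed, with a mean log2 CPM of at least 0 and with both libraries of 1 group above both of the other. It adds the 10 genes with the largest mean change in the same direction in both Dox or both A-MYB contrasts, and up to 4 members per list with the smallest p. The interaction takes 5 genes per direction. For peaks it takes the 10 wild-type-only and the 5 mutant-only regions with the highest smaller fold of their 2 libraries.

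The 23 lists hold 402 genes, 398 of them in the files. They cover naive pluripotency, formative or primed pluripotency, 2-cell-like cells, meiotic prophase, the piRNA pathway, spermatids, spermatogonia, testis somatic cells, the G2/M targets of MYB-MuvB, endoderm, mesoderm, neuroectoderm, trophoblast, fibroblast feeders, the p53 response, the interferon response, the integrated stress response, endoplasmic reticulum (ER) stress, cholesterol synthesis, glycolysis and hypoxia, silencing of endogenous retroviruses, heat shock, and histone genes. Each was tested against the other tested genes with camera (limma; log2 CPM with a prior count of 2, preset inter-gene correlation of 0.01), two-sided, with Benjamini-Hochberg adjustment over the 23 lists of a contrast. The same test with an estimated correlation is given beside it. That test also ended calls of lists whose estimated correlation lay below the preset 0.01. A call lost there thus does not measure correlation between genes alone. Member counts were also adjusted over the list alone, and these counts are printed where they differ from those over all genes.

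Where a gene had 0 counts in a group, its fold is a lower bound set with a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval (Clopper-Pearson on the split of the counts). Intervals and floors cover counting error only.

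Gene counts per library ran from 26995317 to 33771487. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 5.35 to 14.3, and the biological coefficient of variation was 0.0631. The ES cultures were wells of a plate and each spermatocyte preparation came from 1 male mouse; nothing says that ES replicates are separate derivations, so p-values measure only the spread between these samples. The tests were tried on simulated data built from these counts, with 200 of the 14664 genes changed. At a log2 change of 1 the Dox contrast without A-MYB recovered 80%, the Dox contrast with A-MYB 80%, the A-MYB contrasts 76% without and 77% with Dox, and the interaction 66%. At a log2 change of 0.5 they recovered 54%, 56%, 55%, 62% and 39%. False calls made up 10.7%, 4.9%, 9%, 4.8% and 10.3% of their calls. The simulated changes went equally up and down in a single group. In the data the contrasts called 32.2% to 58.9% of genes. The simulated shares of recovered and false calls thus need not hold for the data.

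Peaks of the 4 lists were merged into regions where they overlapped by at least 1 bp (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A region with a peak in both libraries of 1 genotype and in neither of the other is called wild-type-only or mutant-only, and a region with a peak in all 4 is called shared. Simulated regions of each class were all recovered. Per-library values were compared by exact permutation, whose smallest two-sided p with 2 against 2 is 0.333. Regions and genes were compared by two-sided Fisher's exact test with Benjamini-Hochberg adjustment within each family of tests. Only the tests of gene families that share a symbol stem were one-sided. These tests count regions or genes, so their p-values do not measure the spread between libraries. Gene positions came from the annotation of GRCm38.p6, the assembly of mm10, which gave 21887 protein-coding genes and a position for 14601 of the 14664 tested genes. The copy used here holds no strand, so distances planned from transcription start sites were taken instead from either end of a protein-coding gene, within 1 kb. Random placement of each list's peaks within their chromosomes was repeated 100 times. To keep their place in gene-poor or gene-rich parts, the peaks of a list were also moved together by 1 of 100 random offsets of 0.1 to 2 Mb.

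Alternatives tried were DESeq2 size factors and the DESeq2 1.42.0 Wald test, no filter on low counts, a minimum of 2-fold, a fit of only the 4 libraries compared, a replicate block, fry in place of camera, a score of at least 100, lists of equal length (21269 peaks), an overlap of at least 50%, a gene-end window of 5 kb, link distances of 20 kb and 500 kb, and leaving out each library in turn. Scaling by total counts was added after seeing the data. Figures were drawn with matplotlib 3.10.9.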

Results

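Gene expression was measured by RNA-seq in J1 mouse ES cells of 129S4/SvJae background (passage 36, day 3), grown in 2i/LIF medium without feeder cells. All 8 libraries came from cells that carry dCas9-VPR, a catalytically dead Cas9 fused to transcriptional activation domains, with a guide RNA aimed at RLTR10B2, a family of long terminal repeats of endogenous retroviruses. Doxycycline (Dox, 1 µg/ml) was given or left out, and A-MYB, a transcription factor of male germ cells encoded by Mybl1, was expressed or not. This made 4 groups of 2 libraries, called control, Dox, A-MYB and Dox + A-MYB cells. The sum of gene counts was 30588744 and 26995317 in the control libraries, 33771487 and 29735161 in the Dox libraries, 28254102 and 31168253 in the A-MYB libraries, and 30594074 and 30290623 in the Dox + A-MYB libraries. No group analysed here received Dox without the activator or carried another guide, so an effect of the drug itself is part of every Dox contrast.

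H3K27ac, a histone mark of active enhancers and promoters, was measured by ChIP-seq of micrococcal nuclease-digested native chromatin from pachytene spermatocytes of C57BL/6J mice aged 8 to 12 weeks. The cells came from 2 preparations of wild-type mice and 2 of mice homozygous for repro9, a mutant allele of A-myb.

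The Dox + A-MYB libraries stood apart from the other 6. The first principal component (64.1% of the variance of log2 CPM) placed them at 80.71 and 80.86, and the other 6 between -48.42 and -9.73. At least 1 count was found for 17578 ± 33.9 genes in Dox + A-MYB cells (mean ± SD, n = 2), against 16079.5 ± 74.2 in control, 16444.5 ± 95.5 in Dox and 16314 ± 50.9 in A-MYB cells. Reads that the counting assigned to no gene were 9.11 ± 0.452% of all reads in Dox + A-MYB cells, against 7.31 ± 0.0429%, 7.64 ± 0.269% and 7.94 ± 0.563%. The settings of the counting are not given, so these reads need not lie outside annotated genes. Mybl1 itself (gene ID 17864, chromosome 1, 9667407 to 9700439, GRCm38.p6) stood at 7.65 ± 1.04 CPM in control, 10.6 ± 0.581 in Dox, 19.9 ± 2.96 in A-MYB and 18.3 ± 2.32 in Dox + A-MYB cells; the counts do not separate the endogenous gene from an added copy.

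**Figure D1:**
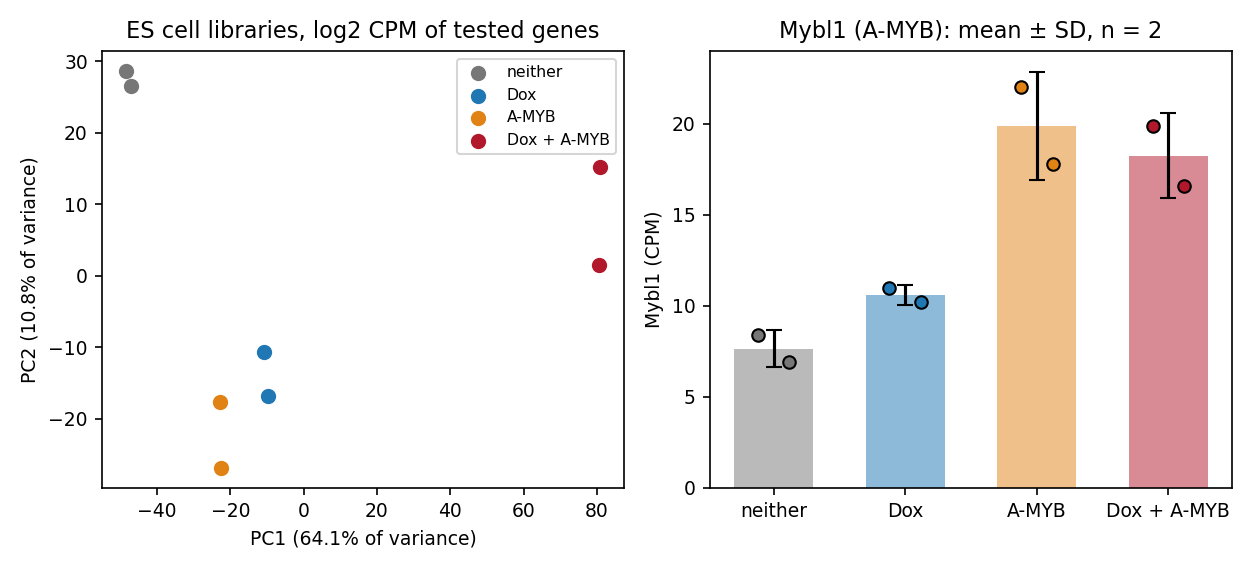
Scores of the first and second principal component of log2 CPM over the tested genes (left) and Mybl1 in CPM (right, bars for group means, points for libraries, error bars for SD, n = 2) in the 4 groups of ES cells, with neither for the control cells. The Dox + A-MYB libraries lie at 80.71 and 80.86 on the first component, which holds 64.1% of the variance, and Mybl1 averaged 7.65 CPM in control and 19.9 CPM in A-MYB cells.

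The first contrast asks which genes respond when the activator aimed at RLTR10B2 is induced in cells without added A-MYB. Slc13a3, which encodes a sodium-dependent dicarboxylate transporter (gene ID 114644, chromosome 2, 165405295 to 165473197), went from 0 counts in both control libraries to 4.59 ± 0.319 CPM in Dox cells (n = 2), at least 83.8-fold higher. Nmnat3, an enzyme of NAD synthesis in mitochondria (chromosome 9, 98287433 to 98420533), rose from 0.398 ± 0.123 to 17.0 ± 0.51 CPM (log2 fold change 5.39, SE 0.21, edgeR adjusted p = 7.31e-16). Lefty1, an antagonist of Nodal signalling, fell from 85.3 ± 0.0953 to 18.6 ± 1.07 CPM (log2 fold change -2.20, SE 0.10, adjusted p = 5.53e-15). Of the 14664 genes tested, 2626 rose and 2091 fell, 337 and 250 of them by at least 2-fold. Which direction held more genes rests on the scaling: with DESeq2 size factors 2294 rose and 2361 fell, and with total counts 3238 and 1731. Mybl1 rose by a log2 of 0.47 (SE 0.15, adjusted p = 0.0167); without control replicate 2 its adjusted p was 0.188 and without Dox replicate 1 it was 0.119.

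Among the other genes with the largest increases, Defb36, a defensin, was at least 28.1-fold higher and Serpina3c, a serine protease inhibitor, at least 27.8-fold higher. Cyp1b1, a cytochrome P450, was 49.2-fold higher (95% interval 13.3 to 412) and Svs4, a seminal vesicle secretory protein, 67.7-fold higher (11.8 to 2710). The chemokine Ccl22 was 31.7-fold higher (5.33 to 1280). Stac3 (log2 fold change 5.86), Sytl4 (5.05), Nrip3 (4.70), the natural killer cell receptor Klrb1a (4.09) and the sodium-activated potassium channel Kcnt1 (2.09) rose as well. Cplx3 was at least 3.52-fold higher (adjusted p = 0.0151), with an adjusted p of 0.102 without control replicate 1, 0.0784 without control replicate 2 and 0.208 without Dox replicate 1. The other large decreases were in Matn1 (-2.89), Gpr133 (-2.74), Wdr86 (-2.68), Nags (-2.51), the lymphotoxin gene Ltb (-2.34), the TGF-beta-induced matrix gene Tgfbi (-2.28), the IGF-binding protein gene Igfbp4 (-2.26), Car5a (-2.21) and Cox7b2 (-2.02).

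Of 31 meiotic prophase genes, 15 rose, 1 fell and 15 did not pass. Taf7l stood at a log2 fold change of 1.59, Tex11 at 1.29, Tex15 at 1.18 and the meiotic cohesin subunit Stag3 at 0.97 (camera adjusted p = 0.00101; adjusted p = 0.0738 with an estimated correlation). Of 20 piRNA pathway genes, which silence transposons in germ cells, 9 rose (10 adjusted over the list alone), 1 fell and 10 did not pass. Piwil2 rose from 11.7 ± 0.573 to 27.4 ± 0.534 CPM, Ddx4 by 1.08 and Mov10l1 by 0.94 on the log2 scale (camera adjusted p = 0.0017; adjusted p = 0.0738 with an estimated correlation). Of 21 genes of 2-cell-like cells, 8 rose, 1 fell and 12 did not pass. Tmem92 stood at 1.54 and Zscan4a, of a family of near-identical copies, at 0.83 (camera adjusted p = 0.0017; adjusted p = 0.11 with an estimated correlation). Of 15 p53 response genes, 8 rose, 3 fell and 4 did not pass. Eda2r stood at 0.99 and Mdm2 at 0.52 (camera adjusted p = 0.0333, and 0.0523 without control replicate 1; adjusted p = 0.137 with an estimated correlation). Naive pluripotency genes did not pass as a list (10 rose, 5 fell and 7 did not pass of 22; camera adjusted p = 0.112), although Dppa3 rose by 1.52 and Klf4 by 0.44.

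Cholesterol synthesis had 17 of 18 genes lower, with Dhcr7 at a log2 fold change of -1.01 and Cyp51 at -0.74 (camera adjusted p = 3.59e-18). In glycolysis and hypoxia, 14 of 16 fell (15 adjusted over the list alone), with Egln3 at -1.12 and Tpi1 at -0.57 (camera adjusted p = 2.01e-11). In the integrated stress response, 13 of 16 fell and 3 did not pass. Trib3 stood at -0.96, Ddit4 at -0.92 and Phgdh, which starts serine synthesis, at -0.81 (camera adjusted p = 2.01e-11). In the ER stress list, 7 of 12 fell and 0 rose (8 and 1 adjusted over the list alone). The chaperone genes stood at -0.80 for Hsp90b1 and -0.58 for Hspa5 (camera adjusted p = 2.86e-05). Of 20 G2/M targets of MYB-MuvB, 7 fell and 2 rose (10 and 2 adjusted over the list alone), with Aurkb at -0.37 and Cdk1 at -0.34 (camera adjusted p = 0.00265). Each of these 5 lists had an adjusted p = 0.0738 with an estimated correlation. Heat shock genes had 4 of 12 lower and 8 that did not pass, with Hspb1 at -0.57 and Hspd1 at -0.37 (camera adjusted p = 0.00443; adjusted p = 0.11 with an estimated correlation). The retrovirus-silencing list did not pass (7 rose, 4 fell and 10 did not pass of 21; camera adjusted p = 0.547), nor did histone genes (2 rose, 3 fell and 7 did not pass of 12; 0.198). Without control replicate 1 the contrast gave 1462 genes higher and 1248 lower, and without Dox replicate 1 it gave 1497 and 1212.

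The second contrast asks what the same induction does in cells that also express A-MYB. Slc13a3 went from 0 counts to 18.5 ± 2.07 CPM (n = 2), at least 355-fold higher, Ccl22 was at least 116-fold higher and Kcnt1 at least 97.3-fold higher. Bnip3, a hypoxia-induced regulator of mitophagy, fell from 285 ± 8.26 to 43.2 ± 3.55 CPM (log2 fold change -2.72, edgeR adjusted p = 1.8e-20), and Loxl2, a collagen cross-linking enzyme, from 16.8 ± 4.99 to 1.16 ± 0.424 CPM (-3.85, SE 0.22, adjusted p = 3.44e-11). In this contrast 4174 genes rose and 4463 fell, 1784 and 542 of them by at least 2-fold. Mybl1 did not pass (log2 fold change -0.12, SE 0.13, adjusted p = 0.427). The split between higher and lower rests on the scaling: with total counts, an alternative added after seeing the data that moves the median of all genes up by 0.21, 6204 genes rose and 2606 fell.

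Serpina3c was at least 92.2-fold and Defb36 at least 47.5-fold higher, Cplx3 190-fold higher (33.7 to 7530) and Svs4 84.8-fold higher (23.2 to 705). Klrb1a (log2 fold change 6.45), Stac3 (6.07), the integrin subunit Itga11 (6.01) and Sytl4 (5.62) also rose. The other large decreases were in Igfbp5 (-3.53), the Wnt antagonist Sfrp5 (-3.46), Fam183b (-3.30), the hypoxia-responsive gene Ndrg1 (-3.23), A2m (-3.19), Nxph4 (-3.19), Aoc3 (-3.14), Ier3 (-2.96) and Adm2 (-2.87). Slc13a3, Ccl22, Serpina3c, Defb36, Stac3 and Sytl4 rose in both Dox contrasts. Across all genes, 1116 rose in both (747.5 expected by chance), 1338 fell in both (636.4 expected) and 825 moved in opposite directions (1394 expected). The log2 fold changes correlated across genes with Pearson's r = 0.492 and Spearman's rho = 0.325, genes not being independent replicates. Without control replicate 1, 699 rose in both, without Dox replicate 1, 865 fell in both, and with total counts 1829 rose and 836 fell in both.

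**Figure D2:**
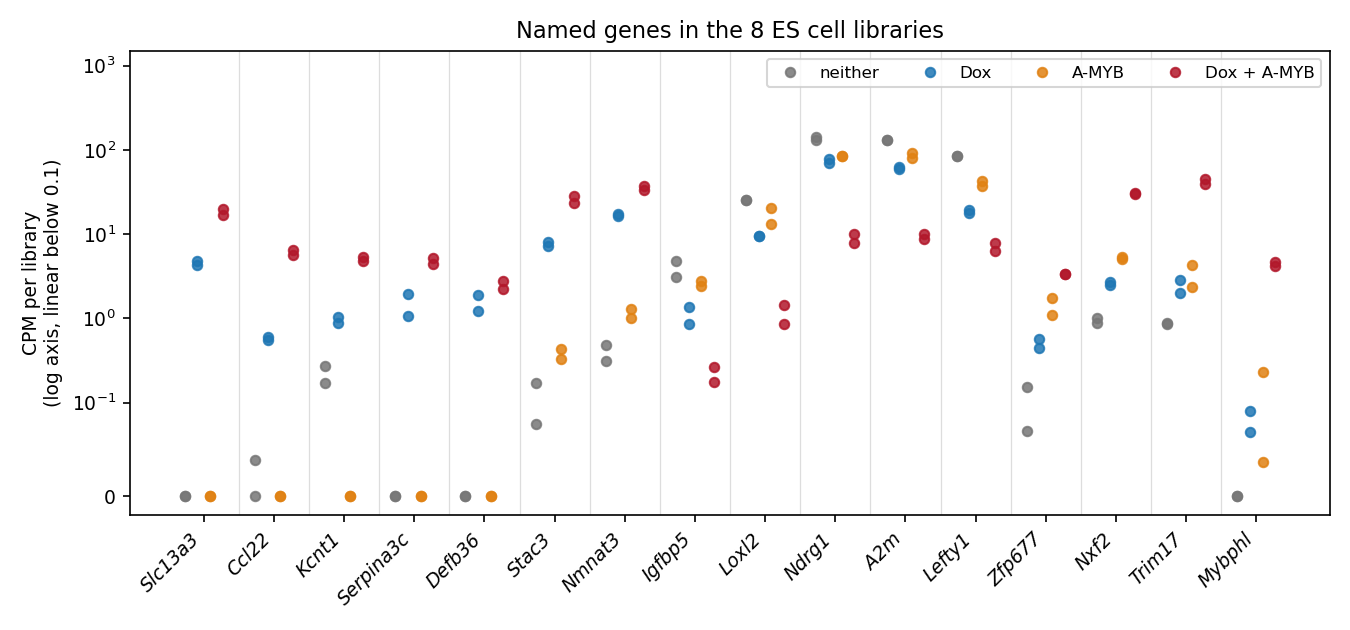
Level of 16 named genes in each ES cell library, in CPM on a log axis that is linear below 0.1, with points per library coloured by group (neither marks the control cells, n = 2 per group). Slc13a3 stood at 0 in the control and A-MYB libraries and averaged 4.59 CPM in Dox and 18.5 CPM in Dox + A-MYB cells, while Lefty1 averaged 85.3 CPM in control and 18.6 CPM in Dox cells.

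Of 31 meiotic prophase genes, 19 rose, 2 fell and 10 did not pass. Msh4, of the meiotic crossover machinery, rose by a log2 of 2.98, Tex101 by 2.50, Taf7l by 1.99 and Stag3, which reached 245 ± 0.436 CPM, by 1.69 (camera adjusted p = 0.00179; adjusted p = 0.0582 with an estimated correlation). In the piRNA pathway 11 of 20 rose, 1 fell and 8 did not pass. Tdrd9 stood at 2.97, Mov10l1 at 1.63 and Piwil2 at 1.19 (camera adjusted p = 0.00179; adjusted p = 0.0582 with an estimated correlation). Of 21 genes of 2-cell-like cells, 10 rose, 2 fell and 9 did not pass. Arg2 stood at 2.08 and Tmem92 at 1.55 (camera adjusted p = 0.0331; adjusted p = 0.229 with an estimated correlation; 0.0658 without Dox + A-MYB replicate 1 and 0.163 with total counts). These lists moved in the cells in which reads assigned to no gene were 9.11% and 17578 genes had at least 1 count. Their medians were 0.74, 0.69 and 0.65. In the lowest group of tested genes by mean CPM (below), the median was 0.92 and 1103 of 2933 genes rose. Ranked by the control libraries, the lowest group had 0.48. With Dox without A-MYB the lowest group by mean CPM stood at 0.06, and the lists at 0.74, 0.49 and 0.67. None of these lists was compared with genes of equal expression. Their rise with Dox in A-MYB cells is thus not set apart from that of genes of low expression.

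All 16 glycolysis and hypoxia genes were lower, with the glucose transporter gene Slc2a1 at -2.0, Pfkp at -1.93 and Hk2 at -1.78 (camera adjusted p = 3.89e-16). In cholesterol synthesis 17 of 18 fell (18 adjusted over the list alone), with Hmgcs1 at -1.79 and Insig1 at -1.74 (camera adjusted p = 2.3e-12). Of 20 G2/M genes, 19 fell and 1 rose, with Kif23 at -1.22 and Ccnb1 at -0.80 (camera adjusted p = 1.15e-07). Of 12 heat shock genes 11 fell, with Hspd1 at -1.37 and Hspa8 at -0.91 (camera adjusted p = 1.16e-06). These 4 lists had an adjusted p = 0.0552 with an estimated correlation. Naive pluripotency genes fell in 16 of 22 and rose in 4. The Nodal co-receptor gene Tdgf1 stood at -1.56, Klf2 at -1.09 and Fgf4 at -1.06, while Dppa3 rose by 1.53 (camera adjusted p = 4.98e-05). ER stress genes fell in 9 of 12 (10 adjusted over the list alone), with Hsp90b1 at -1.37 and Hspa5 at -1.02 (camera adjusted p = 2.47e-05). The naive pluripotency and ER stress lists had an adjusted p = 0.0582 with an estimated correlation. Of 21 genes that silence endogenous retroviruses, 13 fell, 2 rose and 6 did not pass. Uhrf1 stood at -0.88, the H3K9 methyltransferase gene Ehmt2 at -0.50 and Trim28 at -0.38 (camera adjusted p = 0.0141, and 0.163 with total counts; adjusted p = 0.0982 with an estimated correlation). In the highest of 5 expression groups 1706 of 2933 genes fell, with a median of -0.22. The lists were not compared with genes of equal expression. The lists for p53 (8 rose and 3 fell of 15; camera adjusted p = 0.0615), the integrated stress response (3 rose and 9 fell of 16, 4 and 9 adjusted over the list alone; 0.0574) and histones (6 rose and 3 fell of 12, 7 and 3 adjusted over the list alone; 0.245) did not pass.

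**Figure D3:**
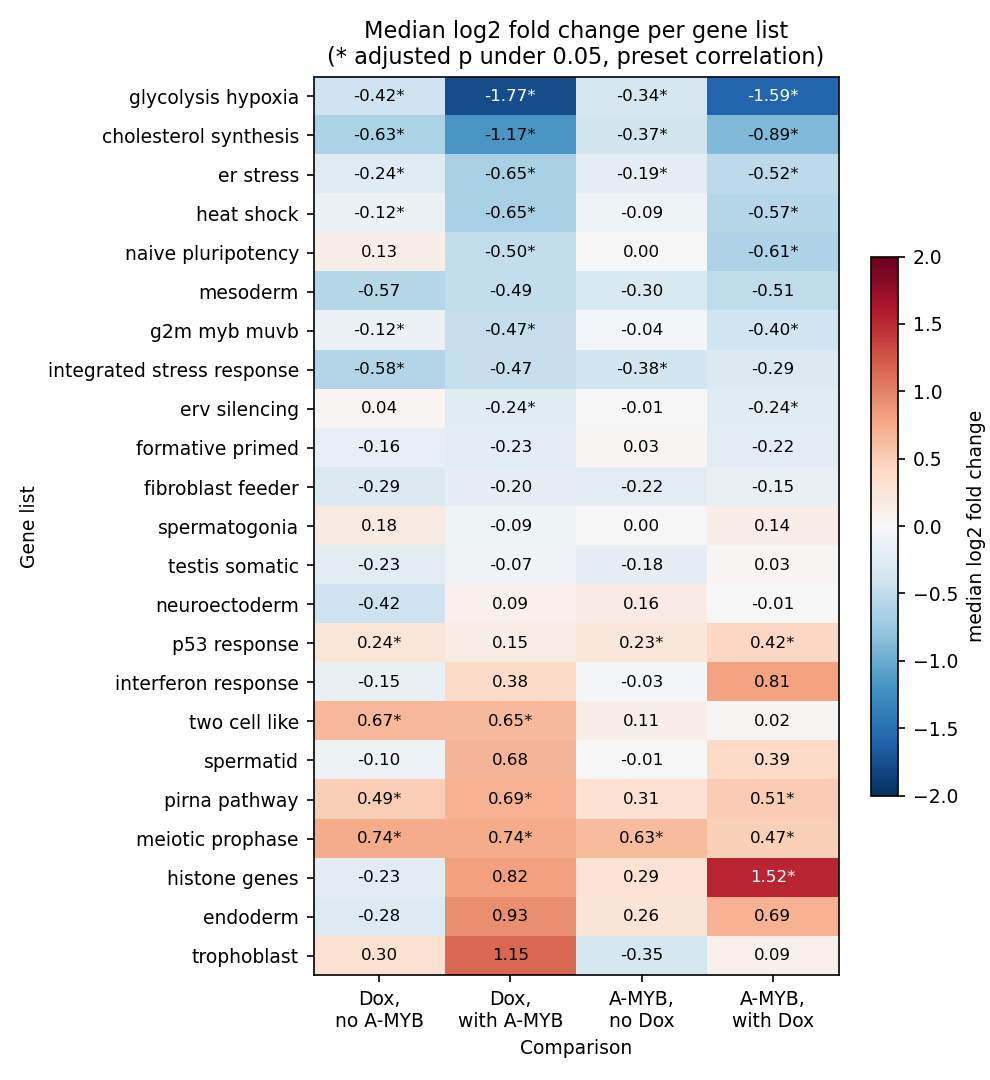
Median log2 fold change of each of the 23 gene lists (vertical) in the Dox and A-MYB contrasts (horizontal), as colour and number, where an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Glycolysis and hypoxia genes had a median of -0.42 with Dox alone and -1.77 with Dox in cells with A-MYB. Meiotic prophase genes stood at 0.74 in both, where the lowest expression group stood at 0.06 and 0.92. With total counts the medians change sign for spermatogonia, testis somatic and fibroblast feeder genes (Dox with A-MYB). They also do for spermatid and retrovirus-silencing genes (A-MYB alone) and for neuroectoderm and fibroblast feeder genes (A-MYB with Dox).

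With Dox in A-MYB cells, genes of low expression rose more often than others. With the tested genes ranked by mean CPM into 5 equal groups, the median log2 fold change ran from 0.92 in the lowest group through 0.20, -0.01 and -0.09 to -0.22 in the highest, and 1076 of 2933 genes of the lowest group rose by at least 2-fold. With A-MYB in Dox cells the medians ran 0.88, 0.20, -0.01, -0.08 and -0.22. With Dox without A-MYB they were 0.06, -0.02, 0.03, 0.05 and 0.02. The mean level of the lowest group was 1.07 ± 0.00442 CPM in Dox + A-MYB cells (n = 2), against 0.593 ± 0.00623 in control, 0.582 ± 0.00806 in Dox and 0.575 ± 0.012 in A-MYB cells. That ranking uses the Dox + A-MYB libraries themselves, so genes expressed mainly there fall into the low groups. With the 13084 genes that had at least 10 counts in both control libraries ranked by those libraries alone, the medians for Dox in A-MYB cells were 0.48, 0.06, -0.03, -0.12 and -0.25, and 702 of the 2617 genes of the lowest group rose by at least 2-fold. For A-MYB in Dox cells they were 0.44, 0.10, -0.02, -0.11 and -0.25. Both rankings were chosen after seeing the data.

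**Figure D4:**
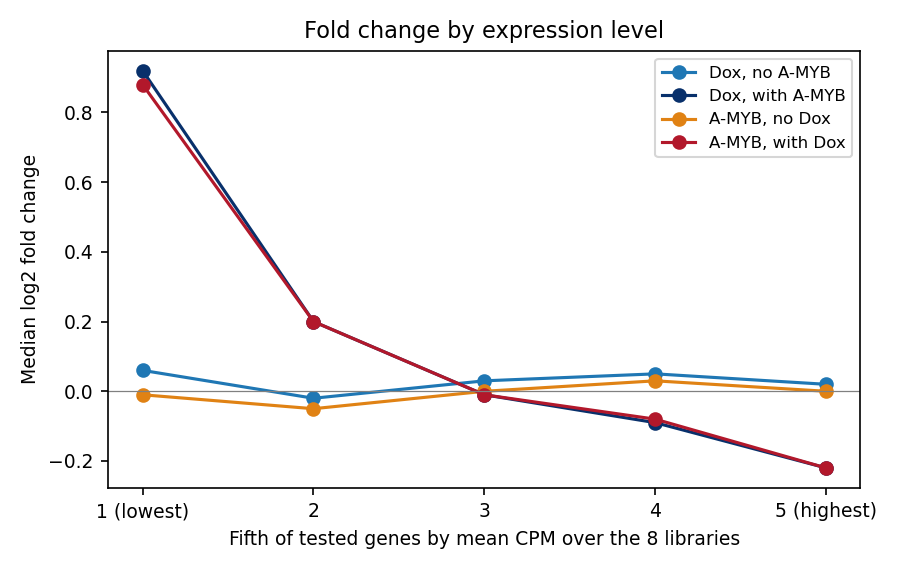
Median log2 fold change (vertical) of the tested genes in 5 equal groups ranked by mean CPM over the 8 libraries (horizontal), for the Dox and A-MYB contrasts, as points joined by lines. The lowest group stood at 0.92 with Dox in A-MYB cells and at 0.06 with Dox alone.

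The third contrast asks what A-MYB does on its own, against the same control libraries as the first. Mybl1 rose from 7.65 ± 1.04 to 19.9 ± 2.96 CPM (n = 2; log2 fold change 1.38, SE 0.14, edgeR adjusted p = 1.24e-07). Zfp677, a zinc finger gene, rose from 0.112 ± 0.0609 to 1.43 ± 0.477 CPM (3.66, SE 0.57, adjusted p = 2.46e-05), and the X-linked RNA export gene Nxf2 (chromosome X, 134944526 to 134964754) from 0.949 ± 0.0783 to 5.23 ± 0.261 CPM (2.45, SE 0.21, adjusted p = 8.24e-09). Cd247, the zeta chain of the T-cell receptor complex, was 11.4-fold higher (2.84 to 99.8), and Kcnt1 at least 4.2-fold lower. Here 2856 genes rose and 2230 fell, 345 and 106 of them by at least 2-fold, against 2653 and 2478 with DESeq2 size factors and 3063 and 1927 with total counts.

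Zfp608 (log2 fold change 2.80) and the ubiquitin ligase gene Trim17 (1.93) also rose, and Kif19a (-1.76), the glycine transporter gene Slc6a9 (-1.73), Selenbp1 (-1.62) and the sperm protease gene Pcsk4 (-1.43) fell; these calls held without each library in turn. Of the 24 genes named here by size of change or by both A-MYB contrasts, Mybl1 included, 13 lost their call when a library was left out. They were Mybphl (at least 2.54-fold higher), Lypd1 (18.1-fold, 2.88 to 752), 4930451G09Rik (7.3-fold, 2.21 to 38), Slc3a1 (3.1), Stk32a (2.96), Plscr2 (2.87), Olfr1372-ps1 (2.69), Entpd1 (2.44), Entpd4 (-1.75), Tnfrsf25 (-1.71), Alox12b (-1.46), Tnnt2 (-1.42) and Gnat2 (-1.38). Without control replicate 1 the adjusted p was 0.128 for Mybphl, 0.169 for Lypd1, 0.0563 for Slc3a1, 0.164 for Entpd1, 0.0652 for Entpd4, 0.102 for Gnat2 and 0.237 for Tnnt2. Without control replicate 2 it was 0.105 for Mybphl, 0.0553 for Lypd1, 0.193 for 4930451G09Rik, 0.0958 for Olfr1372-ps1, 0.13 for Tnfrsf25, 0.109 for Alox12b and 0.0531 for Tnnt2. Without A-MYB replicate 1 it was 0.315 for 4930451G09Rik, 0.0804 for Stk32a, 0.0783 for Plscr2, 0.262 for Olfr1372-ps1, 0.0513 for Entpd1, 0.0515 for Entpd4, 0.117 for Tnfrsf25, 0.0795 for Alox12b, 0.0764 for Gnat2 and 0.188 for Tnnt2. Without A-MYB replicate 2 it was 0.307 for Mybphl, 0.0718 for Lypd1, 0.0551 for Entpd1 and 0.0908 for Tnnt2. Tnnt2, with an adjusted p of 0.0485, also ranged from 0.0557 to 0.0604 without each Dox or Dox + A-MYB library.

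Meiotic prophase genes rose in 12 of 31 with 0 lower (14 and 0 adjusted over the list alone), with Taf7l at 1.51, Hormad1 at 1.35, Tex15 at 1.32 and Stag3 at 0.73 (camera adjusted p = 0.00632; adjusted p = 0.188 with an estimated correlation). The p53 response rose in 9 of 15 and fell in 1, with Trp53inp1 at 1.41, Eda2r at 1.34 and Mdm2 at 0.69 (camera adjusted p = 0.00138; adjusted p = 0.188 with an estimated correlation). Cholesterol synthesis fell in 16 of 18, with Dhcr7 at -0.76 and Mvd at -0.73 (camera adjusted p = 6.31e-09; adjusted p = 0.188 with an estimated correlation). The integrated stress response fell in 11 of 16 with 0 higher (12 and 1 adjusted over the list alone), with Aldh18a1 at -0.70 and Phgdh at -0.68. Glycolysis and hypoxia fell in 12 of 16 (13 adjusted over the list alone), with Vegfa at -0.70 and Pfkp at -0.41 (camera adjusted p = 1.31e-06 for each). ER stress fell in 5 of 12 and rose in 1, with Hsp90b1 at -0.46 and Dnajb9 at 0.78 (camera adjusted p = 0.00878). The last 3 lists had an adjusted p = 0.228 with an estimated correlation. The piRNA pathway did not pass (8 rose and 0 fell of 20; camera adjusted p = 0.0786), although Tdrd9 rose by 1.84 and Piwil2 by 0.61. The lists for 2-cell-like cells (1 rose and 1 fell of 21, 1 and 0 adjusted over the list alone; 0.758), naive pluripotency (4 rose and 5 fell of 22; 0.954), G2/M (4 rose and 6 fell of 20, 5 and 7 adjusted over the list alone; 0.457), retrovirus silencing (7 rose and 4 fell of 21; 0.836), heat shock (1 rose and 4 fell of 12; 0.249) and histones (6 rose and 1 fell of 12; 0.135) did not pass. Without A-MYB replicate 1 the contrast gave 1712 genes higher and 1485 lower; without control replicate 1 it gave 1303 lower, and without control replicate 2, 1442 lower.

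The fourth contrast asks what A-MYB does where the activator is induced, with the same Dox + A-MYB libraries as the second. Sohlh1, a transcription factor of spermatogonia (chromosome 2, 25842995 to 25847248), rose from 0.226 ± 0.0202 to 6.06 ± 0.10 CPM (n = 2; log2 fold change 4.72, edgeR adjusted p = 1.3e-09). Mybphl went from 0.0798 ± 0.0156 to 4.46 ± 0.347 CPM (5.72, SE 0.58, adjusted p = 1.03e-08), Nxf2 from 2.62 ± 0.154 to 30.3 ± 0.709 CPM (3.53, SE 0.15, adjusted p = 7.77e-16) and Trim17 from 2.45 ± 0.601 to 42.0 ± 4.23 CPM (4.09, SE 0.20, adjusted p = 3.49e-12). Mybl1 rose from 10.6 ± 0.581 to 18.3 ± 2.32 CPM (0.79, SE 0.13, adjusted p = 2.31e-05). In this contrast 3935 genes rose and 4161 fell, 1638 and 380 of them by at least 2-fold; with total counts, which moves the median of all genes up by 0.191, 5804 rose and 2367 fell.

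Cd247 (log2 fold change 5.08), Tmem202 (4.61), Itga11 (4.59), Cplx3 (4.08), Gucy2g (3.94), the testis histone gene Hist1h2aa (3.94) and Entpd1 (3.8) were among the largest increases. Lypd1 (2.43), Plscr2 (3.35), Stk32a (3.15), Olfr1372-ps1 (3.26) and Zfp677 (2.70) rose in both A-MYB contrasts. Aoc3 (-3.21), Ndrg1 (-3.03), Loxl2 (-3.02), Ier3 (-2.84), Ppp1r3g (-2.82), Cdc42ep2 (-2.76), A2m (-2.70), Sfrp5 (-2.61), Fam183b (-2.58) and Nxph4 (-2.51) fell the most. Across all genes, 984 rose in both A-MYB contrasts (766.4 expected), 1323 fell in both (632.8 expected) and 929 moved in opposite directions (1409 expected), with Pearson's r = 0.316 and Spearman's rho = 0.245 across genes. With total counts 1520 rose in both and 814 fell in both.

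Meiotic prophase genes rose in 19 of 31 and fell in 2 (20 and 2 adjusted over the list alone), with Msh4 at 2.72, Tex101 at 2.63 and Taf7l at 1.92. The p53 response rose in 10 of 15 and fell in 1, with Ddit4l at 1.48 and Mdm2 at 0.89 (camera adjusted p = 0.00177 for each; adjusted p = 0.0711 with an estimated correlation). The piRNA pathway rose in 9 of 20 and fell in 2, with Tdrd9 at 2.99, Gm13718 (Btbd18, a regulator of piRNA transcription) at 0.99 and Mov10l1 at 0.82 (camera adjusted p = 0.00644; adjusted p = 0.0768 with an estimated correlation). Histone genes rose in 7 of 12 and fell in 2 (9 and 2 adjusted over the list alone). Hist1h1b stood at 2.79, Hist1h2bc at 2.16 and Hist1h1c at 1.64 but H2afx at -0.73 (camera adjusted p = 0.00734; adjusted p = 0.123 with an estimated correlation). These cells are again those with 9.11% of reads assigned to no gene. In this contrast the lowest of 5 expression groups had a median of 0.88, and 0.44 when ranked by the control libraries. The list medians were 0.47 for meiotic prophase, 0.42 for p53, 0.51 for piRNA and 1.52 for histone genes. All 16 glycolysis and hypoxia genes fell, with Bnip3 at -2.22 and Slc2a1 at -2.05 (camera adjusted p = 4.82e-17). So did 17 of 22 naive pluripotency genes against 3 that rose, with Tdgf1 at -1.51, Fgf4 at -1.23 and Nanog at -1.07 (2.24e-07). G2/M genes fell in 16 of 20 and rose in 1 (17 and 1 adjusted over the list alone), with Kif23 at -1.16 (camera adjusted p = 2.09e-06). Heat shock genes fell in 11 of 12, with Hspd1 at -1.28 (3.12e-06). These 4 lists had an adjusted p = 0.0534 with an estimated correlation. Cholesterol synthesis fell in 16 of 18, with Hmgcs1 at -1.43 and Sqle at -1.09 (camera adjusted p = 1.53e-10; adjusted p = 0.0587 with an estimated correlation), and ER stress in 10 of 12 (11 adjusted over the list alone), with Hsp90b1 at -1.03 (camera adjusted p = 0.000219; adjusted p = 0.0768 with an estimated correlation). Retrovirus silencing fell in 13 of 21 and rose in 3, with Uhrf1 at -0.76, Trim28 at -0.57 and Dnmt1 at -0.49 (camera adjusted p = 0.0104, and 0.0676 with total counts; adjusted p = 0.0851 with an estimated correlation), while in the highest expression group 1699 of 2933 genes fell, with a median of -0.22. The lists for 2-cell-like cells (2 rose and 2 fell of 21, 1 and 2 adjusted over the list alone; camera adjusted p = 0.872) and the integrated stress response (5 rose and 9 fell of 16; 0.348) did not pass, although Ddit3 rose by 1.38 and Shmt2 fell by 0.95.

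The interaction asks whether the Dox effect differs with A-MYB. Among the genes that passed, Kcnt1 had the largest fitted positive difference (log2 8.18, SE 1.35, edgeR adjusted p = 3.58e-05): it stood at 0.223 ± 0.0699 CPM in control, 0.955 ± 0.108 in Dox, 0 in A-MYB and 5.09 ± 0.485 in Dox + A-MYB cells (n = 2 each), so that the fitted value rests on a group without counts and is no bound. Car5a (3.33), Gm10532 (3.32) and Tnnt2 (3.28) had a more positive Dox effect with A-MYB, and Mir703 (-3.00), Zfp758 (-2.59), Aoc3 (-2.54) and Snord12 (-2.48) a more negative one. In all, 2410 genes had a more positive and 3586 a more negative effect, 894 and 406 of them by at least 2-fold, and with total counts, which shifts the median by 0.166, 3746 and 2291. Itga11 (4.35, adjusted p = 0.0308) reached 0.808 without control replicate 2, 0.0579 without Dox replicate 1, 0.0624 without A-MYB replicate 2 and 0.133 by DESeq2. Apoo (-2.88, 0.0103) reached 0.0598 without control replicate 1 and 0.0534 without Dox replicate 1. Mybl1 differed by -0.59 (SE 0.20, adjusted p = 0.0183), which became 0.115 without control replicate 2, 0.0705 without Dox replicate 1, 0.152 without A-MYB replicate 1, 0.0815 without Dox + A-MYB replicate 2 and 0.0871 with total counts.

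The Dox effect was more negative with A-MYB for all 16 glycolysis and hypoxia genes (Bnip3 at -2.23 and Slc2a1 at -1.67; camera adjusted p = 2.63e-16), for 16 of 22 naive pluripotency genes against 1 more positive (Tdgf1 at -1.30, Sox2 at -1.05 and Nanog at -1.02; 9.54e-08). It was also more negative for 16 of 20 G2/M genes with 0 more positive (16 and 1 adjusted over the list alone; Kif23 at -1.0 and Cenpf at -0.72; 1.79e-05). These 3 lists had an adjusted p = 0.0719 with an estimated correlation. Heat shock genes were more negative in 11 of 12 (Hspd1 at -1.0; camera adjusted p = 4.95e-05; adjusted p = 0.0779 with an estimated correlation). Cholesterol synthesis was more negative in 13 of 18 and more positive in 2 (13 and 3 adjusted over the list alone; Hmgcs1 at -1.17 and Insig1 at -1.05; camera adjusted p = 7.19e-05; adjusted p = 0.2 with an estimated correlation). Retrovirus silencing was more negative in 11 of 21 and more positive in 1 (Atrx at -0.76 and Setdb1 at -0.51; camera adjusted p = 0.00309; adjusted p = 0.0983 with an estimated correlation). In the highest expression group 1502 of 2933 genes were more negative, with a median of -0.23. The integrated stress response was more positive in 7 of 16 and more negative in 2 (8 and 2 adjusted over the list alone; Ddit3 at 1.38 and Atf4 at 0.70; camera adjusted p = 0.0494; adjusted p = 0.479 with an estimated correlation). Its adjusted p was 0.0692 without control replicate 2, 0.0998 without Dox replicate 1, 0.066 without A-MYB replicate 1 and 0.0516 without A-MYB replicate 2. ER stress was more negative in 7 of 12 and more positive in 1 (Dnajb9 at -1.29; camera adjusted p = 0.035; adjusted p = 0.336 with an estimated correlation). That adjusted p was 0.0609 without control replicate 2, 0.0559 without Dox replicate 1, 0.0566 without A-MYB replicate 2, 0.0793 without Dox + A-MYB replicate 1 and 0.056 with total counts. Meiotic prophase (7 more positive and 4 more negative of 31; 0.388), piRNA (4 and 0 of 20; 0.294), 2-cell-like (1 and 2 of 21; 0.979), p53 (5 and 6 of 15, 7 and 6 adjusted over the list alone; 0.779) and histone genes (4 and 0 of 12, 3 and 0 adjusted over the list alone; 0.0635) did not pass, although Stag3 differed by 0.72 and Tex15 by -1.32.

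The list members named by p are up to 4 per list. Of those that passed, leaving out a library ended the call of 13 of 80 with Dox without A-MYB, 6 of 90 with Dox in A-MYB cells, 20 of 74 with A-MYB without Dox, 5 of 87 with A-MYB in Dox cells and 20 of 77 in the interaction. The members printed here with a value are not among these.

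The other 10 lists, most of them markers of other cell types, did not pass in any of the 5 contrasts. With Dox in A-MYB cells, endoderm genes rose in 5 of 8 and fell in 1 (Cubn at 2.56, Dab2 at 2.42; camera adjusted p = 0.149). Trophoblast genes rose in 6 of 11 and fell in 4 (Rhox6 at 3.09, Krt8 at -0.70; 0.39). Mesoderm genes rose in 2 of 12 and fell in 4 (Wnt3 at 2.54, Wnt3a at -2.30; 0.685). Neuroectoderm genes rose in 2 of 7 and fell in 3 (Pax6 at 1.99, Tubb3 at -1.73; 0.735). Fibroblast feeder genes rose in 3 of 7 and fell in 3 (Twist1 at 1.32, Vim at -1.73; 0.735). Testis somatic genes rose in 3 of 14 and fell in 2 (2 and 1 adjusted over the list alone; Cyp11a1 at 3.16; 0.95). Spermatogonia genes rose in 7 of 14 and fell in 4 (7 and 5 adjusted over the list alone; Sohlh1 at 5.24, Rhox13 at 1.46, Kit at -1.39; 0.778). Spermatid genes rose in 3 of 6 and fell in 1 (Tekt1 at 0.84; 0.491). Formative or primed genes rose in 2 of 13 and fell in 8 (Otx2 at 0.74, Pou3f1 at -1.03; 0.39), and interferon response genes rose in 2 of 7 and fell in 1 (Ddx58 at 0.95; 0.349). In this contrast the median and the mean differed in sign for spermatogonia (-0.09 and 0.49), testis somatic (-0.07 and 0.11), mesoderm (-0.49 and 0.03) and fibroblast feeder genes (-0.20 and 0.29). For neuroectoderm genes the median of 0.09 went with a test toward lower values. Median, mean and test also differed in sign for spermatid and endoderm genes with Dox without A-MYB, and for naive pluripotency, spermatid, spermatogonia, endoderm, fibroblast feeder, interferon response and retrovirus-silencing genes with A-MYB without Dox. The same held for spermatogonia, mesoderm, neuroectoderm, trophoblast and fibroblast feeder genes with A-MYB in Dox cells, and for spermatogonia, mesoderm and neuroectoderm genes in the interaction. With total counts the medians of the spermatogonia, testis somatic and fibroblast lists became 0.12, 0.14 and 0.01. With Dox without A-MYB, trophoblast genes rose in 5 of 11 and fell in 1 (Rhox6 at 2.01, Peg10 at 0.72; camera adjusted p = 0.198) and spermatid genes rose in 0 and fell in 0 of 6 (0.582). With A-MYB in Dox cells, Col3a1 was at least 14-fold higher, while fibroblast feeder genes rose in 3 of 7 and fell in 3 (0.872).

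In spermatocytes the question is which H3K27ac peaks are listed in wild-type and which in A-myb mutant cells. Which library served as treatment and which as control in the peak calls is not given in the sources used here, so it stays open whether a listed peak marks more or less H3K27ac than input. The lists hold 29042 and 24130 peaks from wild-type and 22397 and 21269 from A-myb mutant libraries, covering 46.2, 40.7, 34.9 and 32.0 Mb. Peaks on chromosome Y were 1744 and 1045 in wild-type and 264 and 258 in mutant libraries, or 5.17 ± 1.18% against 1.2 ± 0.0243% of all peaks (n = 2). The share on chromosome X was 8.97 ± 0.177% against 9.12 ± 0.0491%. Exact permutation gave p = 0.333 for Y and p = 0.667 for X, and 0.333 is the smallest p this design allows. The difference on Y was 3.97 percentage points, and 2.69 with lists of equal length, where Y held 874 and 766 wild-type and 238 and 258 mutant peaks. At a score of at least 100 the difference on Y was 1.23 percentage points and that on X 0.03. The shares on Y were lower in all 4 libraries at that score, 1.98% and 1.24% in wild-type and 0.382% and 0.376% in mutant libraries.

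Merging gave 39460 regions, of which 3980 were wild-type-only, 1577 mutant-only and 10838 shared by all 4 libraries. When libraries of different genotype were paired, the same rule gave 1269 and 507 regions in 1 pairing and 943 and 698 in the other. The Jaccard index of covered bases was 0.553 within wild type, 0.460 within mutant and 0.398 to 0.419 between genotypes. Of the wild-type-only regions, 493 (12.4%) lay on Y, against 82 (0.757%) of shared regions (odds ratio 18.55, Fisher's exact adjusted p = 1.83e-200) and 1678 (7.28%) of the 23065 regions of no such class. On X lay 371 (9.32%) against 8.97% (adjusted p = 0.566). Of the mutant-only regions 15 (0.951%) lay on Y (adjusted p = 0.566). The excess of wild-type-only regions on Y restates the difference in Y peaks between the lists, since these lists define the regions. Its Fisher's exact p counts regions rather than libraries, for which exact permutation gave p = 0.333. Leaving out a library, so that its genotype rests on 1, gave 6255 wild-type-only and 2997 mutant-only regions without wild-type replicate 1, 9506 and 2493 without wild-type replicate 2, 6432 and 4012 without mutant replicate 1, and 6197 and 4379 without mutant replicate 2. With the 4 lists set to an equal length of 21269 peaks by score, 2615 regions were wild-type-only and 2234 mutant-only. With a score of at least 100, 3066 were wild-type-only, 514 mutant-only and 2689 shared.

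**Figure D5:**
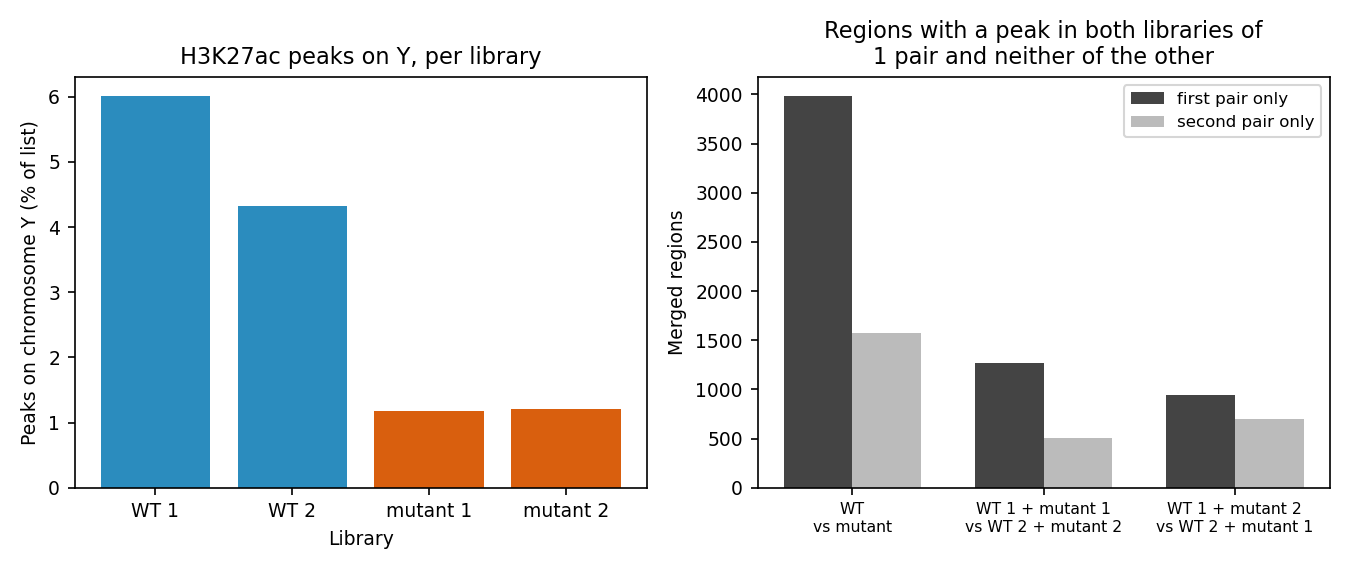
Share of H3K27ac peaks on chromosome Y in percent of each library's list (left), and number of merged regions with a peak in both libraries of 1 pair and neither of the other (right), for the genotype pairing and both mixed pairings. Chromosome Y held 6.01% and 4.33% of wild-type and 1.18% and 1.21% of mutant peaks, and 3980 regions were wild-type-only.

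The folds given here are those listed for the peaks, and the order of the regions rests on their listed direction. The wild-type-only regions with the highest listed fold lay on chromosome 14 at 72891094 to 72892182 near Gm4606 (9.59 and 9.34 in the 2 libraries), on chromosome 1 at 11822408 to 11823445 within A830018L16Rik (9.22 and 8.93) and on chromosome 7 at 104803554 to 104804667 near Usp17le (9.22 and 8.51). The others of the 10 lay within Asah2, Mgat4c and Snrpn or nearest to Gm5800, Vmn1r60, Fut9 and Ctso, with folds between 7.90 and 8.93. The mutant-only regions with the highest listed fold lay on chromosome 4 at 83591287 to 83592230 within Ccdc171 (10.29 and 10.12), within Pde4d (9.62 and 8.97), Cenpp (8.72 and 8.51) and Epm2a (8.95 and 8.28), and nearest to Ankrd50 (8.28 and 10.58).

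Within 1 kb of either end of a protein-coding gene lay 2.88% and 1.98% of wild-type peaks and 1.30% and 1.35% of mutant peaks, while random placement gave 4.83%, 4.97%, 4.92% and 4.86%. Of wild-type-only regions 133 (3.34%) lay there against 1.69% of shared regions (odds ratio 2.01, Fisher's exact adjusted p = 1.47e-08), and of mutant-only regions 1.2% (adjusted p = 0.267). Regions of no such class stood at 3.02%, and random placement gave 4.74% for wild-type-only and 6.04% for shared regions. From the lowest to the highest of 5 groups by listed fold, the share was 6.45%, 3.36%, 1.83%, 1.49% and 1.28% in wild-type replicate 1 and 3.85%, 1.85%, 1.52%, 1.37% and 1.29% in replicate 2. In the mutant libraries only the lowest group stood out, with 1.9%, 1.25%, 1.05%, 1.14% and 1.16%, and 1.86%, 1.25%, 1.25%, 1.27% and 1.13%. The difference in peak share between genotypes was 1.10 percentage points, and 0.312 at a score of at least 100. At that score the genotypes overlapped, with 2.05% and 1.472% in wild-type and 1.42% and 1.475% in mutant libraries, and within 5 kb the wild-type shares of 6.18% and 5.64% lay below the mutant shares of 7.09% and 7.0%. A peak in both wild-type and neither mutant library stood at 131 coding genes, the reverse at 16, and a peak in all 4 libraries at 160. The 131 became 213 without wild-type replicate 1 and 556 without wild-type replicate 2, and 279 with a window of 5 kb. Of the 131, 65 have a provisional symbol, 20 belong to named multi-copy families such as olfactory receptor, keratin-associated and Btbd35f genes, and 46 have another symbol; 24 lie on X and 9 on Y. The 46 include Inpp5d, Med30, Cd200r1, Tlr13, Hspa1a, Hspa1b, Hspa1l, Adam1a and Topaz1, examples picked after their values were seen. By list, 0 of the 23 passed (1 at an unadjusted p under 0.05): 2 of 12 heat shock genes, Hspa1a and Hspa1b, had a wild-type-only peak (Fisher's exact p = 0.00226, adjusted p = 0.0519), as did 1 of 26 spermatid genes, Hspa1l (p = 0.145). Of 35 meiotic prophase and 22 piRNA pathway genes 0 did, beside 0.6% of other coding genes in each test. In the order wild-type replicates 1 and 2 and mutant replicates 1 and 2, any peak stood at 2, 0, 0 and 0 meiotic prophase genes. For piRNA pathway genes it was 1, 1, 0 and 0. With so few peaks, lists of this size cannot show whether wild-type-only peaks are missing there. Of 14 histone genes 3, H2ac4, H2bc4 and H3c2, had a peak in all 4 libraries. Hspa1b, Hspa1a and Hspa1l lie close together on chromosome 17, where Hspa1a ends at 34972156 and Hspa1l starts at 34972703. With a window of 1 kb a single peak can count for both of the latter, so these genes need not be separate hits.

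The last comparison asks whether genes that respond in ES cells lie near regions with a peak only in the wild-type lists. Within 100 kb of a wild-type-only region more than 1 kb from a gene end lay 14.7% of genes that rose with Dox without A-MYB, against 10.9% of the rest (odds ratio 1.42, Fisher's exact adjusted p = 1.35e-07), and 8.34% of those that fell (odds ratio 0.662, adjusted p = 7.54e-07). For A-MYB without Dox it was 16.2% of genes that rose (odds ratio 1.66, adjusted p = 4.63e-16) and 6.25% of those that fell (0.466, adjusted p = 1.01e-18). Mutant-only regions gave odds ratios of 1.27 and 0.687 for Dox and 1.62 and 0.528 for A-MYB, and shared regions 1.4 and 0.738 and 1.74 and 0.549. At a score of at least 100 none of these mutant-only odds ratios passed: they were 1.01 (adjusted p = 0.941) and 0.778 (0.167) for Dox and 1.08 (0.644) and 0.816 (0.284) for A-MYB, with 509 regions in place of 1552. Those of shared regions were then 1.35 and 0.716 and 1.51 and 0.538, and those of wild-type-only regions for A-MYB 1.69 and 0.473. For Dox in A-MYB cells the odds ratios near wild-type-only regions were 0.874 (adjusted p = 0.0307) and 1.02 (0.694), and for A-MYB in Dox cells 0.963 (0.563) and 0.852 (0.0118). At 20 kb the odds ratio for genes that rose with Dox without A-MYB was 1.28 (adjusted p = 0.112), and at a score of at least 100 it was 1.16 (0.0885). For Dox in A-MYB cells, genes that rose had 0.841 (0.261) at 20 kb and 0.881 (0.091) at a score of at least 100, and genes that fell had 1.09 (0.026) at 500 kb. For genes that fell with A-MYB in Dox cells it was 0.791 (0.112) at 20 kb. For genes that rose with A-MYB without Dox, wild-type-only, mutant-only and shared regions gave 1.73, 1.80 and 1.49 at 20 kb. At 500 kb they gave 1.80, 1.55 and 2.47. For genes that fell they gave 0.408, 0.562 and 0.515 at 20 kb, and 0.60, 0.682 and 0.521 at 500 kb. Which class had the odds ratio furthest from 1 thus changed with the distance.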

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

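All tests of explanations in this part were chosen only after the result they address was seen.

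The Dox effect differed with A-MYB for 5996 of 14664 genes (edgeR interaction). Among the named genes, the fitted log2 difference was 8.18 for Kcnt1, which is no bound since Kcnt1 had 0 counts in A-MYB cells (its Dox effect there was at least 97.3-fold). It was 4.35 for Itga11, 3.33 for Car5a, 3.32 for Gm10532 and 3.28 for Tnnt2, and it was -3.00 for Mir703, -2.88 for Apoo, -2.59 for Zfp758, -2.54 for Aoc3, -2.48 for Snord12 and -0.59 for Mybl1. The calls of Itga11, Apoo and Mybl1 ended without single libraries: Itga11 had an adjusted p of 0.808 without control replicate 2, 0.0579 without Dox replicate 1 and 0.0624 without A-MYB replicate 2. Apoo had 0.0598 without control replicate 1 and 0.0534 without Dox replicate 1. Mybl1 had 0.115 without control replicate 2, 0.0705 without Dox replicate 1, 0.152 without A-MYB replicate 1 and 0.0815 without Dox + A-MYB replicate 2. Reads assigned to no annotated gene, which no comparison of expression uses, were 7.64% in Dox, 7.94% in A-MYB and 9.11% in Dox + A-MYB cells, all above the 7.31% of control cells.

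Genes of low expression were higher in the cells with both Dox and A-MYB. Scaling between libraries moves all genes alike, so it neither makes nor removes a gap between groups of genes. With genes filtered and ranked by the control libraries, which the contrast does not use, the lowest and the highest of 5 groups were compared. For Dox in A-MYB cells the median log2 fold change of the lowest minus that of the highest was 0.73. The scalings tried moved the median of all genes by up to 0.21, which leaves this gap as it is. How far low groups rose and high groups fell does rest on the scaling. Genomic DNA carried over in the RNA would be counted alike over silent and transcribed genes, but the gain per olfactory receptor gene (1122 genes) was 0.457% of the gain per gene of that lowest group, and the extraction included removal of genomic DNA. What stays open is the culture or library preparation of that group: 2 libraries, both of the group, lay above all 6 others in the mean level of the lowest group, and since the group has no library from another culture or preparation, this cannot be told apart from a response to Dox and A-MYB together. That joint response, which the design names, could account for the pattern and was not tested separately.

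H3K27ac peaks on chromosome Y were more numerous in the wild-type libraries. Longer wild-type lists do not account for it: with lists of equal length by score, the smaller wild-type number of Y peaks was still 2.97 times the larger mutant number. Round spermatids, which follow meiosis and which the mutant is expected to lack, could add peaks to the wild-type fraction despite the sorting by sedimentation; 1 of 26 spermatid genes had a wild-type-only peak where 0.155 would be expected (Fisher's exact p = 0.145). That gene, Hspa1l, starts within 1 kb of the end of the heat shock gene Hspa1a, so its peak may not be its own. With 1 spermatid gene this explanation cannot be told apart from a difference in H3K27ac on Y between the genotypes, which the design names. Its direction is open as well: with the roles of ChIP and input reversed in the peak calls, more wild-type peaks would mean less H3K27ac there.

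H3K27ac peaks lay less often near gene ends than random placement gives, in all 4 libraries. A genome build other than that of the annotation would leave the peaks as often near gene ends as the same peaks moved together by an offset, but the library nearest to its moved peaks lay 10.3 SD below them (100 offsets). A removal of peaks near genes before deposit might account for the pattern if the density fell at a fixed distance; the largest ratio between neighbouring distance bins was 1.56, and in wild-type replicate 1 the density went from 0.603 of random within 1 kb down to 0.464 at 1 to 2 kb. Since removal with no fixed distance would look the same, it cannot be told apart from the roles of input and ChIP library in the peak calls, which are not given in the sources used here. No biological explanation was tested, since the pattern is in both genotypes.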

How the results depend on the processing

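Total-count scaling was chosen only after the data were seen; all other alternatives were planned. Of 7743 recomputed values of named genes, 7423 kept their direction and side of the threshold, 277 lost a call, 42 gained one and 1 reversed: Fn1 with Dox in A-MYB cells went from -0.20 to 0.01 (adjusted p = 0.913) with total counts. Of 1380 for gene lists, 1279 kept theirs, 59 lost and 42 gained a call. With total counts, 2606 genes fell with Dox in A-MYB cells and 2367 with A-MYB in Dox cells. The interaction gave 3746 and 2291, the Dox overlap 1829 higher and 836 lower, and the A-MYB overlap 1520 and 814. The median of all genes moves with this scaling. At least 2-fold, a stricter limit by construction, passed 337 higher and 250 lower genes for Dox alone, 1784 and 542 for Dox with A-MYB, 345 and 106 for A-MYB alone, 1638 and 380 for A-MYB with Dox, and 894 and 406 for the interaction. With an estimated correlation camera passed 0 lists in each of the 5 contrasts. In the order Dox alone, Dox with A-MYB, A-MYB alone, A-MYB with Dox and interaction, 9, 9, 5, 10 and 5 had an unadjusted p under 0.05. Correlation alone does not account for this loss. The G2/M list with Dox in A-MYB cells had an estimated correlation of -0.017, below the preset 0.01. Its unadjusted camera p still went from 1.51e-08 to 0.00349. In the same order fry, which tests lists without comparing them with other genes, passed 15, 21, 10, 17 and 12. Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 1462 to 2620 higher and 1212 to 2621 lower genes for Dox alone, 3537 to 4150 and 3812 to 4387 for Dox with A-MYB. They were 1712 to 2829 and 1303 to 2866 for A-MYB alone, 3142 to 3986 and 3403 to 4164 for A-MYB with Dox, and 1793 to 2679 and 2856 to 3496 for the interaction. The Dox overlap ran from 699 to 1069 higher and 865 to 1644 lower, the A-MYB overlap from 679 to 1042 and 890 to 1689, and the lists that passed, in the same order, from 9 to 11, 9 to 12, 6 to 8, 11 to 11 and 6 to 10. Counts moved by over 1.5 times without control replicate 1 (1462 and 1248 for Dox alone, 1303 lower for A-MYB alone, 699 in the Dox overlap), control replicate 2 (1442 lower for A-MYB alone), Dox replicate 1 (1497, 1212 and 865) and A-MYB replicate 1 (1712 and 1485). Replicate numbers do not pair the samples (correlation of paired residuals -0.0269 to 0.0843); a replicate block left all 115 list results (23 lists in 5 contrasts, passed or not) and 557 of 561 named genes on their side of the threshold, 3 weaker and 1 stronger. For peaks, a score of at least 100 gave 514 mutant-only and 2689 shared regions and differences (wild type minus mutant, percentage points) of 1.23 on Y, 0.03 on X and 0.312 near gene ends. Equal lists gave 2615 wild-type-only regions and 2.69 on Y, and a 5 kb window 279 genes with a wild-type-only peak. Without single libraries there were 6197 to 9506 wild-type-only, 2493 to 4379 mutant-only and 11741 to 13219 shared regions, 175 to 556 genes with a wild-type-only peak, 0 lists, and differences of 3.135 to 4.809 on Y, -0.279 to -0.028 on X and 0.648 to 1.555 near gene ends. The odds ratio near wild-type-only regions for genes that rose with Dox alone was 1.28 at 20 kb and 1.16 at a score of at least 100; for Dox with A-MYB it was 0.841 and 0.881 for genes that rose and 1.09 at 500 kb for genes that fell; for genes that fell with A-MYB in Dox cells it was 0.791 at 20 kb. Where no cause is named, the cause was not tested. Depth limits folds of genes with 0 counts in a group to lower bounds.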

Other observations

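The tests of gene families, of the X chromosome and of expression groups were chosen only after the data were seen; the test of neighbouring genes was written before its result.

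Families of tested genes that share the stem of their symbol were compared with all other tested genes for the share at least 2-fold higher or lower (83 families of at least 15 genes, 664 one-sided Fisher's exact tests, each direction tested separately, Benjamini-Hochberg adjusted). Histone genes with the stem Hist were higher with A-MYB in Dox cells in 38 of 51, or 74.5% against 10.9% of other genes (adjusted p = 3.34e-23), with Hist1h4i at a log2 fold change of 2.32 and Hist3h2a at 2.06, and with Dox in A-MYB cells in 27 of 51 (adjusted p = 4.46e-10). With A-MYB alone they were higher in 7 of 51 (adjusted p = 0.0163), with Hist1h1b at 1.97. As background, mRNAs of replication-dependent histones mostly lack a poly(A) tail and their copies are near-identical. Zinc finger genes (Zfp) were higher with A-MYB alone in 37 of 345, or 10.7% against 2.14% of other genes (adjusted p = 2.74e-12), with Zfp750 at 1.47, Zfp938 at 1.44 and Zfp160 at 1.24, and with Dox alone in 20 of 345 (adjusted p = 0.0163), with Zfp287 at 1.90. Collagen genes (Col) were lower with Dox alone in 7 of 29, or 24.1% against 1.65% (adjusted p = 7.05e-05), with Col4a1 at -1.41 and Col18a1 at -1.12. Cytochrome P450 genes (Cyp) were higher with A-MYB in Dox cells in 11 of 26, or 42.3% against 11.1% (adjusted p = 0.00679), with Cyp27a1 at 2.19, and Ccdc genes with Dox in A-MYB cells in 29 of 121, or 24% against 12.1% (adjusted p = 0.0189), with Ccdc13 at 2.70. The families were not compared with genes of equal expression, but the shares of 5 expression groups can be set beside theirs. The group with most genes at least 2-fold higher was the lowest, with 998 of 2933 for A-MYB in Dox cells and 1076 of 2933 for Dox in A-MYB cells (659 and 702 of 2617 when ranked by the control libraries). With A-MYB alone it held 131 of 2933, and with Dox alone no group had more than 115 of 2933 genes lower. The shares of Hist genes in the 3 contrasts, of Zfp genes with A-MYB alone and of Col genes lie above these. Those of Ccdc genes and of Zfp genes with Dox alone (5.8%, beside 167 of 2933) are not set apart from genes of low expression. That of Cyp genes lies above the lowest group but rests on 26 genes. The shift of either other scaling moves all genes alike and is smaller than the median of each of these families, so no median could change sign.

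X-linked genes were at least 2-fold higher with A-MYB alone in 35 of 533, or 6.57%, against 2.18% of other genes (odds ratio 3.16, Fisher's exact adjusted p = 5.49e-07), with Eda2r at 1.34, Mmgt1 at 1.32, Diap2 at 1.23 and Taf7l at 1.51. With A-MYB in Dox cells 65 of 533, or 12.2%, were, against 11.1%.

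A hypothesis is that activation spreads between neighbouring genes, as an enhancer active on several promoters might give. Genes within 50 kb of a gene at least 4-fold higher were at least 2-fold higher with Dox alone in 11 of 226, or 4.87%, against 2.26% of other genes (odds ratio 2.21, 1.08 to 4.09), and with A-MYB alone in 18 of 144, or 12.5%, against 2.23% (odds ratio 6.25, 3.54 to 10.4). The odds ratios were 1.25 (1.07 to 1.44) for Dox in A-MYB cells and 1.49 (1.27 to 1.74) for A-MYB in Dox cells. The condition written beforehand for the hypothesis was an interval for Dox alone above that for A-MYB alone, and it was not met. The condition written against it, an interval for Dox alone below a low limit, was not met either. In Dox + A-MYB cells Kcnt1 and Sohlh1, which lie next to each other on chromosome 2 (25863791 to 25918273 and 25842995 to 25847248), both rose. Related genes often lie in clusters and share reads or regulation, and these were not separated here, so shared activation cannot be told apart from families that move together.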
